A study of Arabidopsis thaliana with 14 samples.

How the data were processed

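Gene expression was measured with Affymetrix Arabidopsis ATH1 arrays in whole light-grown seedlings, 14 arrays in 6 groups. Columbia and csn5a-1 had 3 arrays each, with biological replicates numbered by the labels. Wassilewskija, Wassilewskija + DTT, CSN8 and CSN8 + DTT had 2 arrays each, and the labels put 1 array of each of these groups in batch 1 and 1 in batch 2. Columns were matched to samples by the sample identifier that heads each column.

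The deposited values are log2 expression summaries of probe sets, made with RMA per the submitters' processing notes; the RMA software and version are not given in the sources used here. RMA combines background correction, quantile normalization and a summary of the probes of each probe set. The values were checked for their scale and were all positive. Sorted values of any 2 arrays differed by a median of 0.016 to 0.076 within the 6 Columbia and csn5a-1 arrays. The median difference was 0.012 to 0.054 within the 8 other arrays and 0.472 to 0.534 between these sets, so the 2 sets look quantile-normalized separately. Comparisons within a set were therefore made on that set alone, and the comparisons that span both sets carry this limit where they are printed.

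The table held 22810 probe sets. The 64 control probe sets were left out, which left 22746 for testing. The platform annotation gave exactly 1 gene for 13513 probe sets (13355 loci), several genes for 503 and no gene name for 8730. Symbols and loci came from the reference gene table, which held 13436 of the 13513. Only 1580 probe sets carried a gene symbol other than the locus. The annotation used here gave no single-gene probe set for CSN5A (AT1G22920) or COP9 (AT4G14110, which encodes CSN8), so the mutant labels were not checked on the mutated genes.

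Each comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes) on the deposited log2 values, with group means and no other covariate. The 6 arrays of Columbia and csn5a-1 formed 1 fit and the 8 arrays of Wassilewskija and CSN8 another, in which the 4 groups shared 1 estimate of the spread because each had only 2 arrays. The difference between the 2 mutant effects and the comparison of the wild types used all 14 arrays. Tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the probe sets tested, and an adjusted p under 0.05 counted as past the threshold, with no minimum fold. Changes are log2 differences with the limma standard error (SE); levels are log2 means with the standard deviation (SD) over arrays. The number of arrays limits the precision of every value.

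Before the data were examined, 24 gene lists with 475 loci were fixed, of which 65 loci had a single-gene probe set. Lists with at least 3 measured members, 10 in number, were tested with camera on 1 probe set per locus (the one with the highest mean), with a preset inter-gene correlation of 0.01, and again with an estimated correlation, and with fry; Benjamini-Hochberg ran over the lists within a comparison. For each list the members past the threshold over all probe sets are given, and beside it the number past it when adjusted over the list alone. The rule for naming genes was fixed at the same time. It took the probe sets with 1 gene, and named the 8 largest increases and 8 largest decreases with a symbol among those past the threshold with groups that did not overlap. It also took up to 3 members per list with the largest change past the threshold or, where none passed, the member with the smallest p as a value that did not pass. Where no probe set passed, it took the 5 smallest p-values in each direction. Other list members are named where their list is described. Gene families by symbol stem (23 with at least 10 members, the plastid genome among them), the genes shared by the mutants and 4 marker lists (late embryo and seed, flower and anther, pollen, seed reserve mobilisation) were chosen after seeing the data.

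Calls shared by 2 comparisons were counted per direction, with a Fisher exact test against all 22746 probe sets and the number expected from independent lists. The comparisons set side by side in this way have no array in common. Those within the Wassilewskija and CSN8 set still share batches and 1 estimate of the spread, so they are not independent. The comparisons of csn5a-1 and of CSN8 with their wild types come from separate fits. In the set with batches, the change of each named gene was also computed within each batch. Deviations of equally numbered arrays from their group means correlated with r of 0.07 to 0.57 in that set, where the shared number is a batch per the labels.

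The fit was tested on simulated data with 100 changed probe sets of each size among 22746. At a log2 change of 2, limma recovered 93 of 100 for csn5a-1 against Columbia, 72 for CSN8 against Wassilewskija, 72 for DTT in Wassilewskija, 68 for DTT in CSN8 and 37 for the difference between the DTT effects. At a log2 change of 1 the numbers were 52, 26, 36, 25 and 1. The simulated noise was independent between arrays, without batches, and few probe sets were changed. These numbers are therefore not the recovery rates of the real comparisons.

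The alternatives were quantile normalization, median centring of arrays, leaving out the dimmer probe sets, eBayes with trend and robust, array weights, all 14 arrays in 1 fit, only the 4 arrays of the compared groups, the replicate or batch number as a block, a log2 change of at least 1, an adjusted p under 0.01, 1 probe set per locus, an estimated correlation, the mean of the probe sets of a locus, and leaving out each array in turn. A value that passed the threshold under neither of 2 settings was counted as unchanged, since no direction was claimed for it. Raw array files were not used here.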

Results

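The series profiled 12-day-old Arabidopsis seedlings of 2 wild types, Columbia and Wassilewskija, and of 2 mutants of the COP9 signalosome (CSN), a protein complex that removes the ubiquitin-like protein RUB from cullin ubiquitin ligases. The csn5a-1 mutant affects CSN5A, the subunit that carries the catalytic site, and is compared with Columbia (3 arrays each). The mutant labelled CSN8, after another subunit, is compared with Wassilewskija (2 arrays each), and both were also sampled with the label DTT (2 arrays each). DTT is the usual abbreviation of dithiothreitol, a reducing agent that disturbs protein folding in the endoplasmic reticulum. The labels give neither its dose nor its duration, and their shared treatment text speaks of no treatment for any sample. The accession background of the CSN8 mutant is not stated either. All seedlings grew on agar plates with 16 h light and 8 h dark per day. Arrays of the same group correlated across probe sets with r of 0.978 to 0.996. The 95% interval of a change had a median halfwidth of 0.32 log2 units for csn5a-1 and of 0.48 for the comparisons with 2 arrays per group.

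The first question was which transcripts differed between csn5a-1 and Columbia seedlings. Transcripts of the plant defensin PDF1.2 (AT5G44420), a gene known to respond to jasmonate and ethylene, were 35.0-fold higher in csn5a-1 (log2 level 9.68 ± 0.37 against 4.55 ± 0.48, SD, n = 3 each; adjusted p = 2.21e-05). Its relative PDF1.2b rose by 3.07 ± 0.33. In contrast the thionin THI2.1 (AT1G72260), another jasmonate-responsive defence gene, was at least 88.2-fold lower (3.17 ± 0.22 against 9.64 ± 0.26; adjusted p = 4.16e-06). Its level in csn5a-1 is near the lower end of the measured values, so the fold is a lower bound. It was also near that end in Wassilewskija and CSN8, in arrays of the other set, so among these groups only Columbia had a high level. The sugar transporter gene SAG29 (AT5G13170) changed by -5.04 ± 0.13, the defensin-like LCR67 by -5.2 ± 0.23, the glucosinolate biosynthesis gene AOP3 by -4.55 ± 0.27 and the peroxidase gene PRX52 by -4.19 ± 0.19. Other large increases were those of the cold-regulated COR27 (3.9 ± 0.13), ECS1 (3.84 ± 0.43) and the transcription factor gene UPB1 (3.45 ± 0.23). The ubiquitin ligase gene RING1 (3.28 ± 0.23), the immune receptor gene CSA1 (3.12 ± 0.15) and the MADS box gene AGL87 (2.7 ± 0.25) also rose.

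Among the heat shock genes, 4 of 7 measured members fell in csn5a-1, also 4 adjusted over the list alone, among them HSP17.6C (AT1G53540, -1.75 ± 0.27), HSA32 (-1.55 ± 0.2) and HSP26.5 (AT1G52560, -0.64 ± 0.18). The list as a whole did not pass camera (median -0.64, adjusted p = 0.179). Of 4 redox genes, 2 rose and 1 fell (3 adjusted over the list alone). UPOX (AT2G21640), a mitochondrial protein gene used as a marker of oxidative stress, rose by 2.79 ± 0.16 and the zinc finger gene ZAT10 (STZ) by 0.97 ± 0.27, while the glutathione reductase gene GR1 fell by 0.62 on the log2 scale. In the auxin list, IAA29 rose (0.68 ± 0.18), LBD16 (-1.44 ± 0.14) and GH3.5 (WES1, -0.82 ± 0.22) fell, and 4 of 7 members did not pass. The count adjusted over the list alone was 3. All 3 measured cell cycle genes changed, also adjusted over the list alone. The mitotic kinase genes AUR1 and AUR2 moved apart (1.16 ± 0.11 and -1.59 ± 0.15), and the replication helicase gene MCM7 (PRL) fell (-1.02 ± 0.13). Of 6 flavonoid genes, UGT78D2 (-0.72 ± 0.18) and UGT75C1 (AT4G14090, -0.55 ± 0.13) fell, 2 adjusted over the list alone. In the photosynthesis list LHCB4.3 rose (2.07 ± 0.36) and LHCB4.2 fell (-0.88 ± 0.13), and 2 of 4 members passed adjusted over the list alone. The median (-0.17) and mean (0.21) of that list differ in sign. Of 8 genes of the unfolded protein response, ERDJ3B rose (0.75 ± 0.16), DER1 fell (-0.61 ± 0.17) and 6 did not pass. Adjusted over the list alone 3 were past the threshold. With the replicate number as a block in limma, DER1 (adjusted p = 0.0514) and ZAT10 (adjusted p = 0.0504) did not pass.

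Lists with few measured members gave single genes. The meiotic recombination gene MND1 (ATMND1, AT4G29170), the only measured member of the DNA damage list, rose by 2.55 ± 0.14. GSTU25 (1.32 ± 0.14), SAG101 (1.49 ± 0.33), the proteasome subunit gene RPN12A (0.46 ± 0.14) and the root expansin gene EXPA7 (0.7 ± 0.21) were higher. RPN12A did not pass in limma with the replicate number as a block (adjusted p = 0.0649). The sulfate assimilation gene APS4 (-1.35 ± 0.18), the cold-responsive COR15A (-2.14 ± 0.15) and the light signalling gene HYH (-1.12 ± 0.32) were lower. CSN5B, the paralogue of CSN5A and the only measured signalosome subunit, differed by 0.34 ± 0.2 (adjusted p = 0.248), and CUL4 by 0.23 ± 0.18 (adjusted p = 0.384). In total 7474 of 22746 probe sets passed the threshold in limma, 3649 higher and 3825 lower in csn5a-1, of which 2617 changed by a log2 of at least 1. No fixed list passed camera in this comparison, which sets a list against the other genes. The fry test, which asks only whether the genes of a list moved on balance one way, passed for 6 of the 10 lists. Its adjusted p was 0.0019 for redox, 0.0462 for sulfate assimilation, and 0.0336 each for heat shock, auxin, abscisic acid and cell cycle genes. The 3′ minus 5′ signal of the actin control probe sets was 4.95, 4.56 and 3.93 in the csn5a-1 arrays and 3.35 to 3.67 in Columbia. The median plastid-encoded transcript level was 9.91, 8.77 and 8.09 in csn5a-1 against 9.57 to 9.7 in Columbia.

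Several of the strongest decreases were genes of late seed development: the LEA protein genes M17 (AT2G41260, -4.22 ± 0.17) and LEA4-5 (AT5G06760, -4.06 ± 0.1), and the β-glucosidase gene BGLU19 (-3.86 ± 0.24). The fixed seed storage list had 0 of 11 members measured, so a broader late embryo and seed list was written after these genes were seen. Of its 39 measured members, 31 were lower in csn5a-1, 3 higher and 5 did not pass, with a median change of -2.9. Among the 33 members not seen before, 25 were lower and 3 higher, with a median of -2.15. The members that were higher in csn5a-1 were PAP85 (1.01 ± 0.21), AT4G36700 (1.49 ± 0.39) and M10 (0.58 ± 0.13). They belong to the 33 members not seen before the list was written, and are named here for their direction. The median level of the list was 6.8 ± 0.23 (SD, n = 3) in Columbia and 4.33 ± 0.09 in csn5a-1. It was 4.5 ± 1.13 in Wassilewskija and 4.12 ± 0.23 in CSN8 (n = 2 each), in arrays of the other set. Within that set the list differed between batches. Its medians in batches 1 and 2 were 3.7 and 5.3 in Wassilewskija, 3.37 and 5.13 in Wassilewskija + DTT, and 3.25 and 4.83 in CSN8 + DTT. In CSN8 they were 4.28 and 3.96. None of its members passed in any comparison among the Wassilewskija and CSN8 arrays, but this spread between batches limits what those tests could detect.

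**Figure D1:**
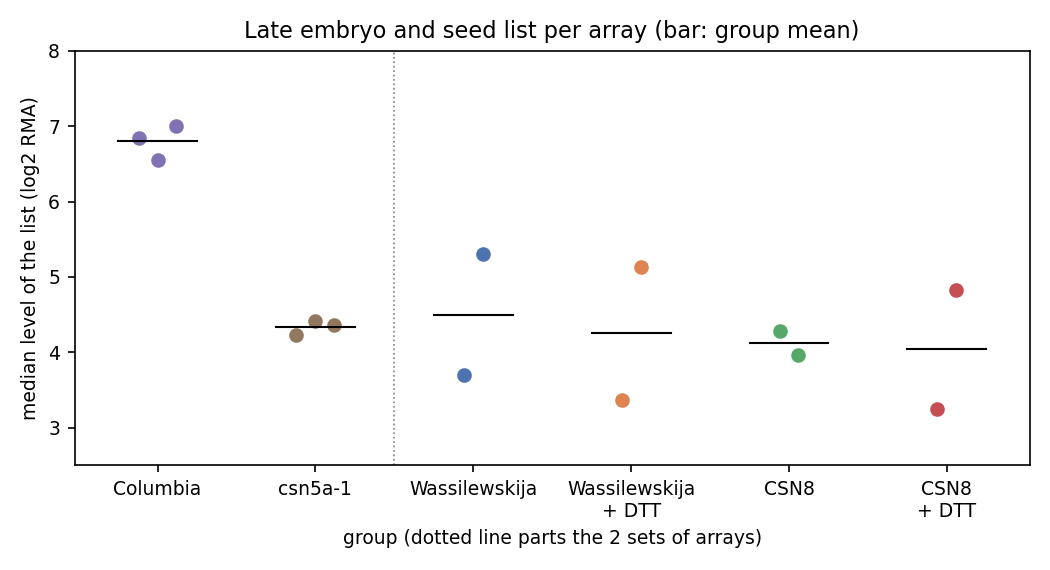
Median log2 RMA level of the 39 measured members of the late embryo and seed list on each array (points) by group, with bars at the group means; the dotted line parts the 2 sets of arrays, which differ in their value distributions. The 3 Columbia arrays lie at 6.55 to 7, and the 3 csn5a-1 arrays at 4.23 to 4.41.

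The next comparison asked which transcripts differed between the CSN8 mutant and Wassilewskija. Transcripts of the anthocyanin pathway gene DFR (AT5G42800), which encodes dihydroflavonol reductase, were at 9.07 ± 0.74 in CSN8 and 3.8 ± 0.25 in Wassilewskija (SD, n = 2 each), a log2 change of 5.26 ± 0.4 (adjusted p = 0.00216; 5.97 and 4.56 within batches 1 and 2). In the flavonoid and anthocyanin list 4 of 6 measured members rose, 5 adjusted over the list alone, with UGT75C1 at 2.62 ± 0.3, UF3GT at 1.52 ± 0.29 and UGT78D2 at 1.28 ± 0.28; 5MAT (0.79, adjusted p = 0.0895) and UGT78D1 (0.77, adjusted p = 0.282) did not pass. The list passed camera (median 1.4, adjusted p = 6.78e-06) but had an adjusted p = 0.13 with an estimated correlation; fry gave 0.00397. The chalcone isomerase-like gene CHIL, which is outside the list, rose by 2.36 ± 0.17. Further increases were those of GH9B11 (3.99 ± 0.29), the ferroxidase gene LPR1 (3.37 ± 0.26) and MND1 (3.26 ± 0.2; 3.14 and 3.37 within batches). The isocitrate lyase gene ICL (3.08 ± 0.45), LHCB4.3 (2.94 ± 0.34), the plastid protease gene SPPA (2.4 ± 0.22) and UPOX (2.05 ± 0.28) were also higher.

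Transcripts of the glucosyltransferase gene UGT73B5 (AT2G15480) were lowered by the largest amount among the named genes, at 3.84 ± 0.53 in CSN8 against 8.24 ± 0.7 (-4.41 ± 0.36; -5.28 and -3.54 within batches). Other decreases were those of GT72B1 (-2.97 ± 0.17), the expansin gene EXPA8 (-2.86 ± 0.42), the transporter gene OCT5 (-2.76 ± 0.23) and the asparaginase gene ASPGB1 (-2.71 ± 0.57). BZIP61 (-2.57 ± 0.4), UGT74B1 of glucosinolate synthesis (-1.45 ± 0.29) and GH3.5 (-1.36 ± 0.23) also fell. The co-chaperone genes Fes1A (-2.9 ± 0.28) and Hop3 (-2.56 ± 0.33) fell. In the heat shock list 1 of 7 members, HSP23.5 (AT5G51440, -2.59 ± 0.52), fell over all probe sets and 2 adjusted over the list alone. That list passed camera (median -0.55, adjusted p = 0.00573), with an adjusted p = 0.143 with an estimated correlation and 0.0369 in fry. In the abscisic acid and dehydration list none of 3 members passed over all probe sets and 2 did adjusted over the list alone, with COR15A at -0.77 ± 0.21. That list had a median of -0.96 (camera adjusted p = 0.0396), an adjusted p = 0.411 with an estimated correlation and 0.143 in fry. At the preset correlation its adjusted p was 0.0576 under quantile normalization and 0.0606 under median centring, and ranged from 0.0301 to 0.0722 over the alternatives that kept all arrays. It ranged from 0.00193 to 0.337 when 1 array was left out, and the call was lost without Wassilewskija of batch 1 (0.337), CSN8 of batch 1 (0.0578) or CSN8 of batch 2 (0.118). For the redox list, with UGT73B5 and UPOX past the threshold in opposite directions (2 of 4 adjusted over the list alone), the median (0.1) and the mean (-0.54) differ in sign. The same holds for the photosynthesis list (-0.29 and 0.24), in which LHCB4.3 was the only call of 4 members and 2 passed adjusted over the list alone. None of the 3 cell cycle genes passed over all probe sets, and all 3 did adjusted over the list alone. None of the 8 genes of the unfolded protein response passed, also adjusted over the list alone, and BZIP60 differed by -0.68 ± 0.26 (adjusted p = 0.191). CSN5B differed by 0.3 ± 0.19 (adjusted p = 0.437).

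In limma 1327 probe sets passed between CSN8 and Wassilewskija, 646 higher and 681 lower, and 2706 with the batch as a block (1297 higher, 1409 lower). Across probe sets the changes within batch 1 and batch 2 correlated with r of 0.58. At least 2-fold changes in both batches went the same way for 1083 probe sets and opposite ways for 46. With the block COR15A (adjusted p = 0.0353), AUR1 (1.02, adjusted p = 0.0146 with the block and 0.0881 without) and EXPA18 (-0.97, adjusted p = 0.0095 and 0.0598) also passed. The array CSN8 of batch 1 stood apart in the 3′ minus 5′ signal of the GAPDH control probe sets (1.67, against 0.25 to 0.62 in the other 7 arrays of this set). Without it 408 probe sets passed, and without Wassilewskija of batch 1 426 did.

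With DTT, the same mutant difference was compared between CSN8 + DTT and Wassilewskija + DTT. DFR was again higher in the mutant (9 ± 0.61 against 3.68 ± 0.08, SD, n = 2 each; 5.32 ± 0.4, and 5.8 and 4.83 within batches; adjusted p = 0.00268). ICL (4.16 ± 0.45), GH9B11 (3.59 ± 0.29), the calmodulin-like CML41 (3.05 ± 0.61), LPR1 (2.98 ± 0.26) and the tetraspanin gene TET9 (2.96 ± 0.51) were higher too. So were MND1 (2.85 ± 0.2), CHIL (2.69 ± 0.17), UPOX (2.67 ± 0.28), LHCB4.3 (2.37 ± 0.34) and SAG101 (1.91 ± 0.38). In the flavonoid list 5 of 6 members rose, also 5 adjusted over the list alone, with UGT75C1 at 3.09 ± 0.3 and UF3GT at 2.09 ± 0.29 (median 2.01, camera adjusted p = 1.91e-07; adjusted p = 0.0848 with an estimated correlation and 0.002 in fry). Decreases included UGT73B5 (-3.46 ± 0.36), GT72B1 (-3.1 ± 0.17), EXPA8 (-2.99 ± 0.42), OCT5 (-2.87 ± 0.23) and the auxin glucosyltransferase gene IAGLU (-2.57 ± 0.3). Fes1A (-2.18 ± 0.28), UGT76E11 (-2.14 ± 0.43), BZIP61 (-2.04 ± 0.4), MCM7 (-1.61 ± 0.13) and GH3.5 (-1.59 ± 0.23) were lower as well. None of the 7 heat shock genes passed, with HSP23.5 at -1.21 ± 0.52 (adjusted p = 0.271). The median of that list (0.03) and its mean (-0.23) differ in sign, as do those of the redox list (0.33 and -0.03) and the cell cycle list (0.42 and -0.17). Of the 940 probe sets past the threshold in limma, 474 were higher and 466 lower. With the batch as a block 2045 passed (993 higher, 1052 lower), and 103 without Wassilewskija + DTT of batch 2. Between the comparisons without and with DTT, 679 calls were shared, 678 of them in the same direction, and the changes correlated across all probe sets with r of 0.81. These comparisons share batches and the estimate of the spread, so their agreement is not that of independent experiments.

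**Figure D2:**
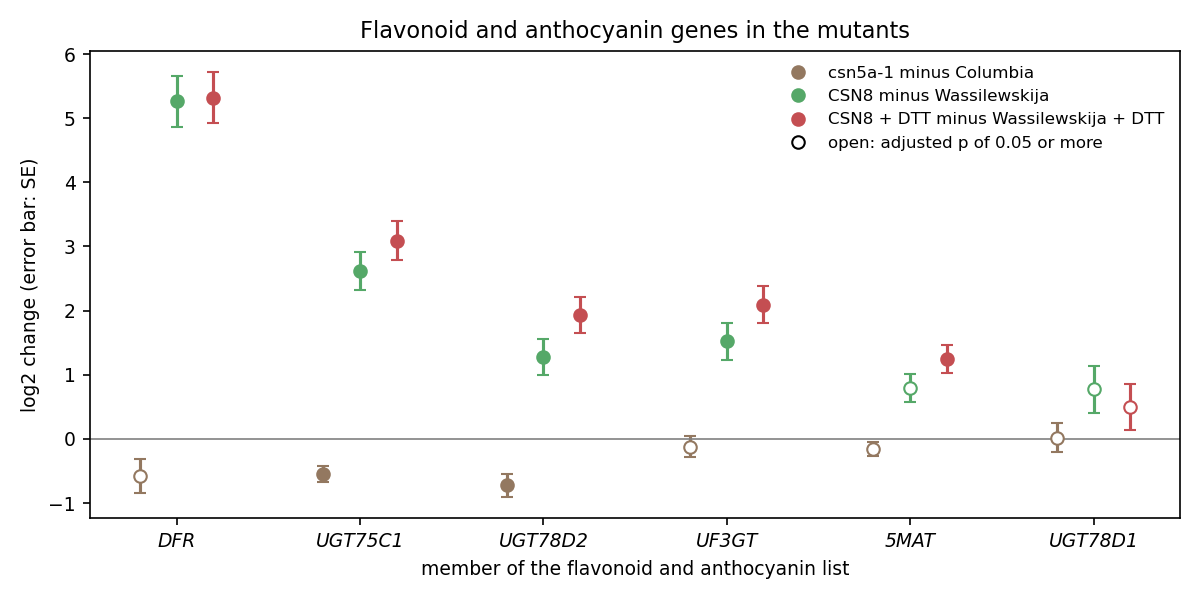
Log2 change (points, with SE bars) of the 6 measured flavonoid and anthocyanin genes in csn5a-1 against Columbia and in CSN8 against Wassilewskija without and with DTT; open points had an adjusted p of 0.05 or more. DFR changed by 5.26 and 5.32 in the CSN8 comparisons and differed by -0.58 in csn5a-1, where it did not pass.

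The DTT comparisons asked which transcripts differed with the DTT label within each genotype. BZIP60, OS9, DER1 and DER2.1, which serve protein folding and quality control in the endoplasmic reticulum, rose with DTT in both. In Wassilewskija the transcription factor gene BZIP60 (AT1G42990), a main regulator of the unfolded protein response, rose from 8.62 ± 0.43 to 11.21 ± 0.38 (SD, n = 2 each; 2.59 ± 0.26, and 2.55 and 2.62 within batches; adjusted p = 0.017). OS9, whose product takes part in the degradation of misfolded proteins, rose by 2.54 ± 0.26, GFAT of hexosamine synthesis by 2.45 ± 0.3, the derlin genes DER2.1 by 2.09 ± 0.23 and DER1 by 1.98 ± 0.2. GPT (1.51 ± 0.18) and SPP (1.37 ± 0.16) rose too. The expansin genes EXPA4 (-2.08 ± 0.23) and EXPA18 (-1.69 ± 0.23), the carboxypeptidase-like SCPL49 (-2 ± 0.19), NAI2 (-1.91 ± 0.24), which is needed for endoplasmic reticulum bodies, and AQI (-1.18 ± 0.16) fell. Of the 2 measured root marker genes, both expansin genes, EXPA18 thus fell and EXPA7 differed by -1.47 ± 0.4 (adjusted p = 0.364). Adjusted over the list alone 2 of 2 were lower, with a median of -1.58. Of the 8 measured genes of the unfolded protein response list, 2 rose over all probe sets and 5 adjusted over the list alone (median 2.03, camera adjusted p = 6.18e-12; adjusted p = 0.105 with an estimated correlation and 0.0145 in fry). The other 3 of these 5 were the calnexin gene CNX2 (2.27 ± 0.32, adjusted p = 0.051 over all probe sets), ERDJ3B (2.26 ± 0.39, 0.102) and the calreticulin gene CRT1B (2.08 ± 0.36, 0.0987). These tests did not take the batch into account. Within batches 1 and 2, CNX2 rose from 6.74 to 9.45 and from 6.74 to 8.59. ERDJ3B rose from 8.8 to 10.93 and from 7.81 to 10.22, and CRT1B from 9.83 to 12.01 and from 9.09 to 11.07. BZIP28 (0.11 ± 0.17), BZIP17 (0.06 ± 0.19) and DER2.2 (0.26 ± 0.16) did not pass over all probe sets or adjusted over the list alone. In the heat shock list none of 7 members passed over all probe sets and 1 adjusted over the list alone, HSP15.7 (AT5G37670, -1.01 ± 0.2). That list had a median of -0.3 (camera adjusted p = 0.004; adjusted p = 0.13 with an estimated correlation and 0.108 in fry). At the preset correlation its adjusted p ranged from 0.0014 to 0.107 over the alternatives that kept all arrays, with 0.107 when the dimmer probe sets were left out. It ranged from 0.000135 to 0.354 when 1 array was left out, with 0.354 without Wassilewskija of batch 1.

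In CSN8, BZIP60 rose by 2.83 ± 0.26 with DTT (10.77 ± 0.1 against 7.94 ± 0.07, SD, n = 2 each; 2.86 and 2.81 within batches; adjusted p = 0.0139). GFAT rose by 2.39 ± 0.3, DER2.1 by 2.22 ± 0.23, OS9 by 2.21 ± 0.26, CNX2 (AT5G07340) by 2.28 ± 0.32 and DER1 by 1.91 ± 0.2. The calmodulin-like CML37 (4.49 ± 0.65) and the tetraspanin genes TET9 (3.45 ± 0.51) and TET8 (2.29 ± 0.22) also rose. Decreases were those of SCPL49 (-2.89 ± 0.19), the β-glucosidase genes BGLU44 (-2.77 ± 0.41) and PYK10 (-2.4 ± 0.31), of EXPA4 (-2.37 ± 0.23) and NAI2 (-1.96 ± 0.24). The genes scpl26 (-1.95 ± 0.28), the subtilase gene SBTI1.1 (-1.88 ± 0.24), AQI (-1.86 ± 0.16) and MCM7 (-0.9 ± 0.13) fell as well. In the unfolded protein response list 3 of 8 members rose over all probe sets and 6 adjusted over the list alone (median 1.88, camera adjusted p = 1.62e-08; adjusted p = 0.19 with an estimated correlation and 0.0133 in fry). The redox list had 0 calls of 4 members over all probe sets and 2 adjusted over the list alone (median 0.8, camera adjusted p = 0.0156; adjusted p = 0.391 with an estimated correlation and 0.197 in fry). At the preset correlation it was 0.115 without CSN8 + DTT of batch 1 and 0.11 without CSN8 of batch 2, in a range of 0.00511 to 0.115 when 1 array was left out. The cell cycle list had 1 call, MCM7, also 1 adjusted over the list alone, with a median of -0.41. Its camera adjusted p was 0.0254, or 0.391 with an estimated correlation, and fry gave 0.0709. Its median was -0.15 without CSN8 + DTT of batch 1, -0.32 without CSN8 of batch 2 and -0.51 without CSN8 of batch 1. For the cell cycle list the adjusted p was 0.087 with the dimmer probe sets left out and 0.0675 with eBayes trend and robust, in a range of 0.0179 to 0.087 over the alternatives that kept all arrays. It ranged from 0.0224 to 0.151 when 1 array was left out, with 0.151 without CSN8 + DTT of batch 1, 0.11 without CSN8 of batch 2 and 0.0678 without CSN8 of batch 1. With the batch as a block, ZAT10 (1.72, adjusted p = 0.0346 with the block and 0.108 without), SAG101 (1.66, 0.022 and 0.118) and EXPA18 (-1.09, 0.0172 and 0.093) also passed. Without the block neither root marker gene passed over all probe sets, with EXPA7 at -1.28 ± 0.4, and 2 of 2 were lower adjusted over the list alone (median -1.18).

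**Figure D3:**
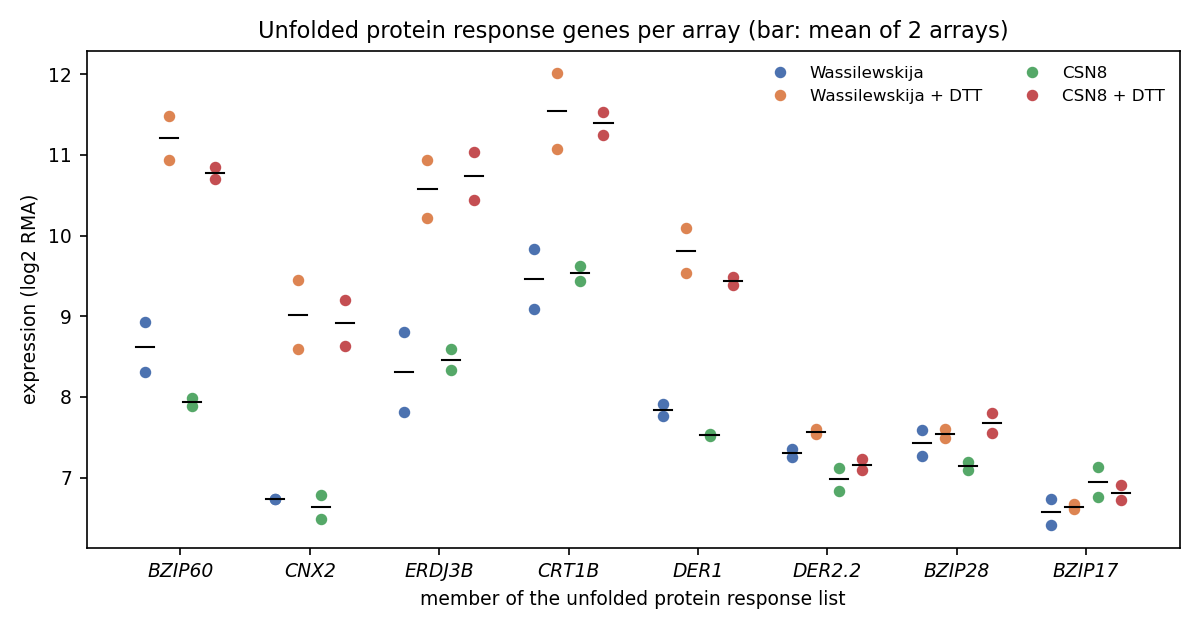
Log2 RMA level of the 8 measured genes of the unfolded protein response list on each of the 8 Wassilewskija and CSN8 arrays, coloured by group, with bars at the mean of 2 arrays. BZIP60 lies at 8.62 and 11.2 in Wassilewskija without and with DTT and at 7.94 and 10.77 in CSN8; BZIP17 differed by 0.06 and -0.13.

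In limma 83 probe sets passed with DTT in Wassilewskija (42 higher, 41 lower; 186 with the batch as a block) and 293 in CSN8 (156 higher, 137 lower; 705 with the block). Of these 63 were called in both, all in the same direction, in comparisons that share batches and the estimate of the spread. Changes correlated between the genotypes with r of 0.63 across probe sets. These counts rest on 2 arrays per group, and they were 1 without Wassilewskija of batch 2 and 2 without CSN8 of batch 1, respectively. The test of the difference between the DTT effects in CSN8 and Wassilewskija called 0 probe sets in limma, with 662 at an unadjusted p under 0.05 and a smallest adjusted p of 0.883. With the batch as a block it also called 0 (1087 unadjusted), and 9 without CSN8 + DTT of batch 2. With all arrays none of the genes above was shown to respond differently in the 2 genotypes. The median 95% halfwidth of this difference was 0.68 log2 units. The smallest p-values belonged to AT3G04640 (2.58 ± 0.36), AT2G27080 (1.93 ± 0.28), AT3G02840 (2.81 ± 0.41), TET8 (2.14 ± 0.32) and AT4G27280 (2.22 ± 0.36) on the positive side. On the negative side they belonged to MCM7 (-1.13 ± 0.19), AT5G52670 (-1.7 ± 0.3), AT3G05390 (-1.03 ± 0.21), psbZ (-1.22 ± 0.27) and AT1G07080 (-0.91 ± 0.2). Over the unfolded protein response list the difference had a median of -0.03 and a mean of 0.02 (camera adjusted p = 0.944), and BZIP60 differed by 0.25 ± 0.37. Heat shock genes had a median difference of 0.58 (camera adjusted p = 0.000475; adjusted p = 0.138 with an estimated correlation and 0.253 in fry) and cell cycle genes of -0.32 (camera adjusted p = 0.00984; adjusted p = 0.374 with an estimated correlation and 0.263 in fry). No member of either list passed over all probe sets. Adjusted over the list alone, 0 heat shock genes and 1 cell cycle gene, MCM7, did. The cell cycle median was 0.02 without Wassilewskija of batch 1 and -0.07 without CSN8 + DTT of batch 1.

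The mutants were then compared with each other, each relative to its own wild type. MND1 was higher in both (2.55 ± 0.14 in csn5a-1 and 3.26 ± 0.2 in CSN8), as were LHCB4.3 (2.07 and 2.94), FU (1.5 and 2.32), SCPL49 (1.52 and 1.27), DI21 (1.42 and 1.55) and the histone gene HTB2 (1.53 and 1.15). EXPA8 (-2.17 and -2.86), Hop3 (-1.99 and -2.56), IAGLU (-1.71 and -2.32), GT72B1 (-1.42 and -2.97) and the cold-responsive COR15B (-1.37 and -2.28) were lower in both. Opposite changes were seen for ICL (-2.87 and 3.08), CHIL (-2.59 and 2.36), the glucosyltransferase gene UGT84A1 (-1.7 and 1.37) and XTH32 (-3.47 and 1.22), which were lower in csn5a-1 and higher in CSN8. The reverse was seen for EXLA1 (2.44 and -1.36), BZIP61 (1.17 and -2.57) and SRC2 (0.98 and -2.34). These shared genes were chosen after their values were seen. Of 692 probe sets called in both mutants, 451 changed in the same direction and 241 in opposite directions. In both mutants 240 were higher, against 104 in independent lists (Fisher exact p = 7.88e-40), and 211 were lower, against 115 (Fisher exact p = 2.18e-20). Those higher in csn5a-1 and lower in CSN8 numbered 113, against 109 (Fisher exact p = 0.672). Those with the reverse pattern numbered 128, against 109 (Fisher exact p = 0.0424). The Fisher test treats probe sets as independent units, so these p-values do not measure the spread between arrays. Across all probe sets the changes correlated with r of 0.12, and with the block 1352 calls were shared, 864 of them in the same direction. Without Wassilewskija of batch 1, 236 calls were shared (174 in the same direction, 62 opposite), and without CSN8 of batch 1, 246 (171 and 75).

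**Figure D4:**
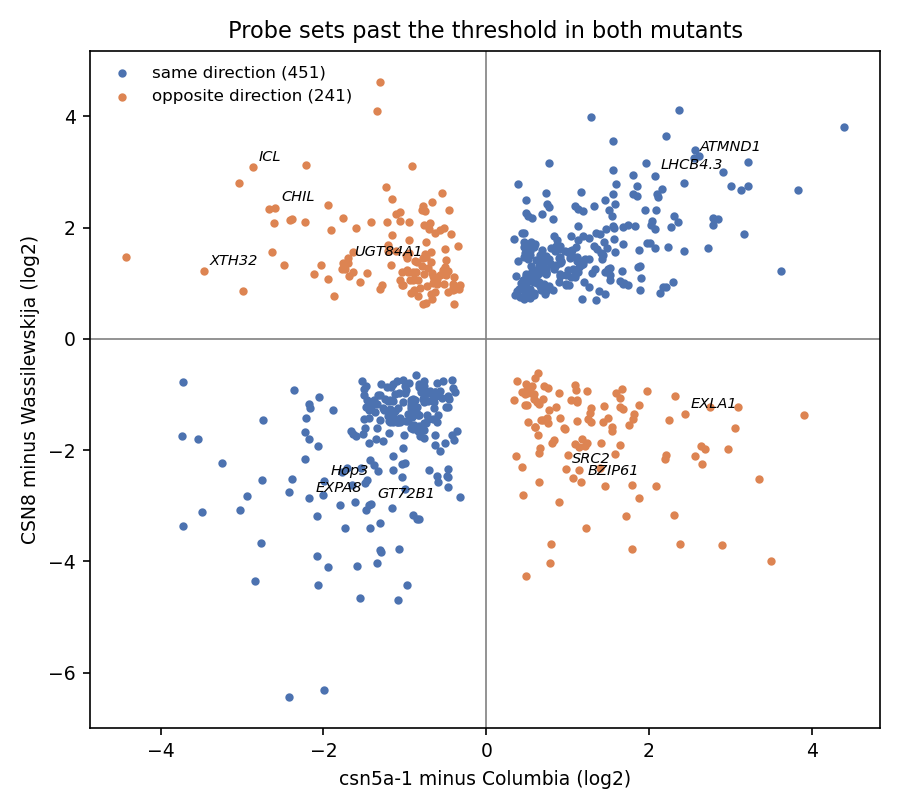
Log2 change in csn5a-1 against Columbia (horizontal) and in CSN8 against Wassilewskija (vertical) of the 692 probe sets past the threshold in both comparisons, with some named genes marked. The 451 blue points changed in the same direction and the 241 orange points in opposite directions.

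A direct test of the difference, the change in CSN8 minus the change in csn5a-1 over all 14 arrays, called 3995 probe sets in limma, 2158 of them positive and 1837 negative, and 2657 without Wassilewskija of batch 1. PDF1.2 differed by -5.68 ± 0.37 (adjusted p = 6.9e-06), DFR by 5.85 ± 0.51 and CHIL by 4.96 ± 0.3. THI2.1 differed by 6.16 ± 0.25 (adjusted p = 6.3e-07), but its level was 2.89 ± 0.12 in Wassilewskija and 2.58 ± 0.08 in CSN8, so a fall like that in csn5a-1 had no room to show. In the flavonoid list 5 of 6 members differed over all probe sets and also adjusted over the list alone, with a median of 1.82 (camera adjusted p = 4.34e-05; adjusted p = 0.121 with an estimated correlation and 0.000117 in fry). In fry alone the redox list (0.0263) and the cell cycle list (0.0083) passed too. Further positive differences were those of ICL (5.95 ± 0.59), SAG29 (5.72 ± 0.31), SWEET13 (5 ± 1.01), LEA18 (4.79 ± 1.39) and XTH32 (4.69 ± 0.31). Negative ones were those of UGT73B5 (-4.13 ± 0.44), COR27 (-4.03 ± 0.54), EXLA1 (-3.8 ± 1) and Fes1B (-3.53 ± 0.38). SAG29 and LEA18 were among the genes that were high in Columbia, with SAG29 at 10.91 ± 0.22. For MND1 (0.7 ± 0.25, adjusted p = 0.0768) and LHCB4.3 (0.86 ± 0.56, adjusted p = 0.335) the difference did not pass. Each mutant was compared within its own set of arrays, so accession, experiment and normalization differ between the effects along with the mutated gene.

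The wild types were compared last. Relative to Columbia, Wassilewskija had less transcript of THI2.1 (-6.75 ± 0.17, a bound because of its level of 2.89 in Wassilewskija), SAG29 (-6.12 ± 0.22), ECS1 (-6.01 ± 0.4), HIS1-3 (-5.52 ± 0.29), BGLU19 (-5.49 ± 1.03), ZW9 (-5.41 ± 0.19), JAL33 (-5.09 ± 0.16) and the iron-regulated BHLH101 (-4.81 ± 0.59). It had more of the subtilase gene SBT4.12 (3.6 ± 0.34), the peroxidase gene Prx37 (3.35 ± 0.26), PRN (3.06 ± 0.46), of SUFE2 (3.03 ± 0.52) and CML38 (2.97 ± 0.87). The glutathione transferase genes GSTU22 (2.96 ± 0.52) and GSTU25 (2.73 ± 0.42), and UGT73C1 (2.73 ± 0.37), were higher too. Both measured root expansin genes, EXPA7 (2.24 ± 0.33) and EXPA18 (1.64 ± 0.18), were higher in Wassilewskija. BGLU19 is a member of the late embryo and seed list, which was high in Columbia. Its level in Wassilewskija was 5.42 ± 2.29 (SD), so the 2 arrays lay far apart. In limma 13271 probe sets passed, 1868 higher and 11403 lower in Wassilewskija. The median of all probe sets was -0.43, and the array medians were 5.93 in the Columbia set and 5.3 in the Wassilewskija set. These values span separately normalized sets, and their split depends on that. After quantile normalization of all 14 arrays 8922 passed, 4447 higher and 4475 lower with a median of 0. After median centring 10130 passed, 6412 higher and 3718 lower with a median of 0.18. Accession and experiment cannot be told apart here, and the array probes follow the Columbia sequence.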

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

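The tests of seed material, of flower or pollen tissue, of reserve mobilisation, of dehydration and of the loss of CSN5A were chosen only after the seed result was seen, as were the gene families. For reserve mobilisation, dehydration and the other splits of the arrays, the bounds were written before the values they measure were seen. No group had more than 3 arrays, so single arrays were not tested for standing apart from their group.

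Late embryo and seed transcripts were higher in Columbia than in csn5a-1, with a median change of -2.15 over the 33 list members not seen first. Flower or pollen tissue in the Columbia samples is argued against: the 14 flower and pollen markers had a median change of -0.11. Their median level was 3.17 in Columbia against 3.01 over csn5a-1, Wassilewskija and CSN8, with arrays of both sets and no centring. The bounds for flower and pollen were written after their values were seen. Seed or embryo material in the Columbia samples may account for the pattern. The bound written for it, a clearly lower median with most members lower, was met, with 25 of the 33 lower. That bound was written after the pattern was seen. In addition PAP85, a seed storage protein gene, AT4G36700 and M10 were higher in csn5a-1, which leaves this explanation open. A lowering by the loss of CSN5A stays open too. With centred arrays csn5a-1 lay at -0.82 and Columbia at 1.68 relative to Wassilewskija over the list. Accession and separate normalization go with that comparison, and the 2 Wassilewskija arrays lay far apart. Their list medians were 3.7 in batch 1 and 5.3 in batch 2 before centring, so the value of -0.82 rests on an uneven reference. The stage of reserve mobilisation (1 unseen member, SDP1, at 0.25) and a vegetative dehydration response (3 list members, median -0.33) rest on too few genes to decide.

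The 6 arrays of csn5a-1 and Columbia can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 7474 calls and the highest of the others gave 0. Every other split puts arrays of both groups on each side, so group differences widen its spread. Its 0 calls therefore do not show what arrays without a group difference would give.

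The remaining results of this part are differences between the effects of 2 groups, tested in limma or with camera. Between the CSN8 and csn5a-1 effects 3995 probe sets differed. Positive differences among the named genes were THI2.1 6.16, ICL 5.95, DFR 5.85, SAG29 5.72, SWEET13 5, CHIL 4.96, LEA18 4.79, XTH32 4.69, UGT75C1 (AT4G14090) 3.17, AUR2 2.1, HYH 2.01, UGT78D2 1.99, APS4 1.9, LBD16 1.43, COR15A 1.38, GR1 1.25 and HSA32 1.21. Negative ones were PDF1.2 -5.68, UGT73B5 -4.13, COR27 -4.03, PDF1.2b -3.86, EXLA1 -3.8, BZIP61 -3.73, Fes1B -3.53, TBL45 -3.34, ROF2 (AT5G48570) -2.55, GSTU25 -2.17, COR47 -1.72, EXPA7 -1.57, EXPA18 -1.36, UGT74B1 -1.08 and BZIP60 -0.91. With the replicate and batch numbers as a block UGT74B1 did not pass (adjusted p = 0.0556). THI2.1 was at 2.89 in Wassilewskija, where a fall like that in csn5a-1 had no room to show. By list or family, the median difference was 1.82 for the flavonoid list, which lost its camera call with an estimated correlation (adjusted p = 0.121). It was -0.73 for the VPS genes of vacuolar sorting (camera adjusted p = 0.0247, or 0.501 with an estimated correlation). For the plastid genome it was 1.01 (camera adjusted p = 0.000418, or 0.809 with an estimated correlation). The plastid result did not pass without CSN8 replicate 1, and its csn5a-1 side was uneven, with array medians of 9.91, 8.77 and 8.09 beside actin 3′ minus 5′ signals of 4.95, 4.56 and 3.93.

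Between the DTT effects in CSN8 and Wassilewskija the median difference was 0.58 for the heat shock list and -0.32 for the cell cycle list. The cell cycle median was 0.02 without Wassilewskija replicate 1, -0.07 without CSN8 + DTT replicate 1 and -0.18 without Wassilewskija + DTT replicate 2. It was -0.15 for the GH family, -0.1 for the SCPL family, 0.3 for the tetraspanin (TET) family and -0.62 for the plastid genome, all arrays kept. The plastid difference includes CSN8 replicate 1, with a plastid median of 8.83. The GAPDH 3′ minus 5′ signal of that array was 1.67, against 0.25 to 0.62 in the other arrays of that set. The families had camera adjusted p of 0.0309, 0.0309, 0.000535 and 2.16e-11, and each had an adjusted p = 0.483 with an estimated correlation, while no single gene passed. Over the alternatives at the preset correlation that kept all arrays the adjusted p ranged from 8.62e-05 to 0.00263 for the heat shock list and from 0.00747 to 0.042 for the cell cycle list. The lists had an adjusted p = 0.138 and an adjusted p = 0.374 with an estimated correlation, and 0.253 and 0.263 in fry. In camera at the preset correlation it was 0.0518 and 0.302 without Wassilewskija replicate 1. For the cell cycle list it was also 0.129 without CSN8 + DTT replicate 1, 0.175 without Wassilewskija + DTT replicate 2 and 0.0996 without CSN8 replicate 2.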

How the results depend on the processing

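The estimated correlation, the array left out and the other settings below were planned; only the seed list without the loci seen first (median -2.15 against -2.9) was chosen after the result was seen. Apart from leaving out 1 array, the alternatives kept direction and call of the 195 gene results past the threshold in 1676 of 1899 values. They lost the call in 219, of which 42 came from fits on only the 4 arrays of the compared groups. The direction reversed in 4, all for Wassilewskija minus Columbia under median centring: CUL4 0.0685, AT1G43140 0.248, AT2G32730 0.0262 and RCA 0.2359. The 12 called lists kept the call in 87 of 108 values and all 12 lost it with an estimated correlation, as did all 35 family calls (251 of 315 kept). With 1 array left out, 392 of 1944 gene values, 14 of 102 list values and 52 of 284 family values lost the call. Unless noted, the cause was not tested. Counts are in the order csn5a-1, CSN8, CSN8 + DTT, DTT in Wassilewskija, DTT in CSN8. An adjusted p under 0.01, a stricter threshold, gave 4294, 290, 198, 9 and 6, 1872 for the difference of the mutants and 113 shared calls. With 1 probe set per locus, fewer tests, they were 4055, 614, 448, 42 and 160, then 2053, 7860 for the wild types and 310 shared. A log2 of at least 1 left 2617 in csn5a-1, 5691 for the wild types and 328 shared, and leaving out dim probe sets 6742 for the wild types. Array weights gave 836 in CSN8 and 1435 in CSN8 + DTT, and eBayes trend and robust 132 for DTT in Wassilewskija. All 14 arrays in one fit gave 2746, 2080, 258 and 755 from CSN8 on and 1229 shared; only the 4 arrays of the 2 groups, fewer arrays, gave 289, 624, 2 and 3. The batch as a replicate block gave 2706, 2045, 186 and 705, and 1352 shared. For csn5a-1 and Columbia only the replicate number is shared (r of 0.04 to 0.07 between equal numbers; 5 of 6 arrays correlated best with their own number), and the block gave 6925 instead of 7474 calls. Over all comparisons the block ended 12 named gene calls and added 6. It added 1 list (abscisic acid, Wassilewskija minus Columbia, camera adjusted p = 0.019) and changed no other call of a named gene or fixed list. Among all probe sets, 6514 of the 7474 csn5a-1 calls stayed with the block. Leave-one-out, in which a group left with 1 array is assumed to vary like the others, gave 5421 to 7221 for csn5a-1, 408 to 1035 for CSN8, 103 to 806 for CSN8 + DTT, 1 to 63 for DTT in Wassilewskija, 2 to 246 for DTT in CSN8, 0 to 9 for the difference of the DTT effects, 2657 to 3962 for that of the mutants, 10156 to 13566 for the wild types and 236 to 740 shared. Counts moved most without Wassilewskija replicate 1 (426 in CSN8, 41 for DTT in Wassilewskija, 2657, 236 shared) and 2 (702, 1, 387 shared), Wassilewskija + DTT replicate 1 (838, 181 in CSN8 + DTT, 3, 99 for DTT in CSN8) and 2 (838, 103, 14, 99), CSN8 replicate 1 (408, 2 for DTT in CSN8, 246 shared) and 2 (92 for DTT in CSN8), and CSN8 + DTT replicate 1 (879, 163, 39, 11) and 2 (879, 490, 39, 9 for the difference of the DTT effects).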

Other observations

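The family results below were chosen after the data were seen. In csn5a-1 7 of 14 measured genes of the sugar transporter family SWEET fell, with SWEET4 at -3.01 ± 0.15, SWEET13 at -2.95 ± 0.28 and SWEET2 at -1.28 ± 0.13 (family median -0.34, camera adjusted p = 0.0102; adjusted p = 0.783 with an estimated correlation). The other 7 did not pass. The family was formed by symbol stem, so the sugar transporter gene SAG29, which also fell, was not counted. Of 10 VPS genes of vacuolar sorting 7 rose, with VPS20.1 at 1.74 ± 0.16 (median 0.51, adjusted p = 0.0239; adjusted p = 0.783 with an estimated correlation), as did 5 of 10 NET genes of actin binding (median 0.47, adjusted p = 0.0448; adjusted p = 0.783 with an estimated correlation). In CSN8 relative to Wassilewskija, EXPA8 (-2.86 ± 0.42) and EXPA16 (-1.69 ± 0.25) fell among 10 expansins (median -0.49, adjusted p = 0.0397; adjusted p = 0.564 with an estimated correlation). The root marker genes EXPA7 (-0.87 ± 0.4) and EXPA18 (-0.97 ± 0.23) are in that family; neither passed over all probe sets, and EXPA18 did adjusted over the list alone. Also lower were BZIP61 and BZIP53 (-1.22 ± 0.23) among 14 BZIP genes (median -0.28, camera adjusted p = 0.0077, or 0.516 with an estimated correlation). The SWEET family had a median of -0.24 in CSN8 (camera adjusted p = 0.0453, or 0.564 with an estimated correlation), with 1 call. Between CSN8 + DTT and Wassilewskija + DTT its median was -0.36 (camera adjusted p = 0.0221, or 0.738 with an estimated correlation), with 2 calls. Of 69 plastid-encoded transcripts 3 rose in CSN8, rbcL (1.48 ± 0.27), rpoC1 (1.34 ± 0.25) and psbZ (1.03 ± 0.19), and the group had a median of 0.57 (adjusted p = 0.000598; adjusted p = 0.565 with an estimated correlation, and 0.279 at the preset correlation without CSN8 replicate 1). That array stood apart in its GAPDH 3′ minus 5′ signal (1.67, against 0.25 to 0.62 in the other 7 Wassilewskija and CSN8 arrays) and had a plastid median of 8.83, against 8.46 in CSN8 replicate 2.

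With DTT, expansin genes had a median change of -0.65 in Wassilewskija (adjusted p = 2.74e-06; adjusted p = 0.233 with an estimated correlation) and -0.99 in CSN8 (adjusted p = 1.31e-05; adjusted p = 0.184 with an estimated correlation). The 2 measured root marker genes, EXPA7 and EXPA18, are in this family and had medians of -1.58 and -1.18. Serine carboxypeptidase-like (SCPL) genes had a median of -0.22 in Wassilewskija, where 1 of 29 passed (adjusted p = 0.000494; adjusted p = 0.233 with an estimated correlation), and of -0.25 in CSN8, where 5 fell (adjusted p = 1.32e-05; adjusted p = 0.184 with an estimated correlation), among them scpl29 (-1.76 ± 0.28) and SCPL27 (-0.96 ± 0.14). The 10 genes with the symbol stem SEC, which do not share 1 function, had medians of 0.24 and 0.29 (adjusted p = 0.000814 and 0.00914; adjusted p = 0.233 and 0.184 with an estimated correlation), with no member past the threshold on its own. Plastid-encoded transcripts had a median of 0.14 with DTT in Wassilewskija (adjusted p = 0.0167; adjusted p = 0.591 with an estimated correlation, and 0.0552 after median centring) and -0.47 in CSN8 (adjusted p = 7.7e-06; adjusted p = 0.392 with an estimated correlation, and 0.342 at the preset correlation without CSN8 replicate 1).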
